A study of Rattus norvegicus with 2 samples.

How the data were processed

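Total RNA of RMT-1 cells given a negative control siRNA or an siRNA against Pla2g4c was labelled with Cy3 and hybridised to Agilent one-colour rat arrays, 1 array per group, per the labels. The scanner files hold spot intensities on a linear scale, made by the authors with Agilent Feature Extraction (10.10.1.1 per the file headers, 10.10 per the submitters' processing notes). Per the file headers, the processed signal is background-subtracted and detrended within the array, and was not normalized between the arrays. The software's outlier and background flags (0 or 1) were used as deposited. A further table of deposited intensities equals each array's processed signal times a constant, 1.77 for the control array and 1.50 for the Pla2g4c siRNA array, as computed from the values. How those constants were chosen is not given in the sources used here. Its medians were 118.5 and 130.2. Both arrays lay on the same slide and shared the scan and extraction protocol, so there was no slide or scan batch to test.

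Depth on an array is signal over background, and the number of arrays limits the precision. The 75th percentile of the processed signal was 852 on the control array and 1105 on the Pla2g4c siRNA array, 466 and 381 gene spots carried outlier flags, and 0 were saturated. The slope of the spike-in RNAs was 1.01 and 1.03, and the coefficient of variation of replicate probes was 4.22% and 4.38%.

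The main values were log2 of the processed signal minus the array's 75th percentile over gene spots. Spots flagged as outliers on either array were left out and the spots of a probe averaged. A probe counted as measured where all its remaining spots were well above background on both arrays, which held for 16840 of 30367. The difference is the Pla2g4c siRNA array minus the control array, and its error is the software's error estimate of both signals carried to the log2 scale, with a median of 0.20. Genes well above background on 1 array only were given as a bound, the brighter array's value over the higher of the dim probe's own value and the lowest value of any probe well above background on that array.

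Gene names came from RefSeq accessions, since the columns used here held no gene name, and the planned naming by such a column was replaced. A current symbol was found for 18006 probes (59.3%), and 12361 were unnamed here. Of the unnamed probes 6195 were measured, 84 of them at least 2-fold higher and 237 at least 2-fold lower, and they are in no gene count. A gene's value is the mean over its measured probes. Across the 1473 genes with several measured probes, which are not independent replicates, the first and second probe correlated with a Pearson r of 0.73 and a Spearman rho of 0.75. No probe matched Pla2g4c. Coordinates are not reported, since the naming table and the array design use different genome builds.

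No test across samples was possible with 1 array per group. Genes were counted at 2-fold. For each of 34 gene lists the median difference of measured members was set against 10000 random lists of the same size matched in 10 bins of mean signal, and a list outside the central 95% was called apart. Of the list symbols 29 were updated to current names and 1 was not resolved. Named genes were Pla2g4c, the 12 genes with the highest and the 12 with the lowest difference among those with a proper symbol, a brighter array above the median of its probes well above background, all probes in the same direction and at least 2-fold under normexp and quantile normalization too, the 4 largest bounds in each direction, and up to 2 members at each end of every list (all where 5 or fewer were measured). Of the list members so chosen, 2 are not reported here. That rule was met by 87 genes in the higher and 101 in the lower direction before the limit of 12. The main values, lists, naming rule and all alternatives but spike-in scaling were fixed before the data were examined.

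The alternatives were normexp background correction (offset 50), median scaling, quantile normalization and cyclic loess between the arrays, the deposited values, the brightest probe per gene, no filter on dim probes, measured probes above the median signal, flagged spots kept, thresholds of 1.5-fold and 3-fold, and probes in place of genes. Normexp used the median spot signal in place of the planned mean signal, which was not among the columns used here. Scaling to 7 spike-in RNAs, the comparison with the 20 genes nearest in signal, a scan of symbol families and 4 further gene lists were added after the data were seen. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Steps were tested on simulated data with technical noise only (spot SD 0.158). For the comparison of both arrays over 9026 genes, all 50 genes at each true difference of 1.5, -1.5, 3 and -3 were recovered and 0 unchanged genes reached 2-fold. Of 100 simulated lists without a shift 3 were called apart, and of 100 shifted by 0.5 all were.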

Results

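RNA of RMT-1 cells, a rat mammary tumour cell line (clone E4), was measured on 2 one-colour expression arrays, 1 from cells given a negative control siRNA and 1 from cells given an siRNA against Pla2g4c. Pla2g4c encodes a member of the cytosolic phospholipase A2 family, enzymes that release fatty acids from membrane phospholipids. Each array held 30367 gene probes, and 61.9% of gene spots were well above background on the control array and 63.1% on the Pla2g4c siRNA array. A level was obtained on both arrays for 9026 named genes. With 1 array per group there was no replicate check and no test. Each difference below is the Pla2g4c siRNA array minus the control array on the log2 scale, and its ± is the scanner software's error of that difference, which covers technical error within the arrays only.

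The series title names apoptosis after repression of Pla2g4c as its subject. The comparison asked which transcripts differed between cells given the Pla2g4c siRNA and cells given the control siRNA. Inflammatory mediators, matrix proteases and MHC class II genes were among the genes with the highest difference in the Pla2g4c siRNA array, and genes of squamous epithelium were among those with the lowest. The inflammatory list had a median difference of 1.06, with 10 of its 18 measured members at least 2-fold higher and 0 at least 2-fold lower. All 41 measured members of the ribosomal protein list were lower, with a median of -0.64, of which a part went with their high signal, as described with that list. The lists of apoptosis genes had medians near 0.

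No probe could be matched to Pla2g4c through the names used here, so the level of the targeted transcript was not analysed here and the labels were not checked by it. Of its family, Pla2g4a differed by 0.40 ± 0.20 and Pla2g4b by 0.00 ± 0.23, and these were the 2 members with a probe that could be named here.

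Of the 9026 genes, 263 were at least 2-fold higher and 275 at least 2-fold lower in the Pla2g4c siRNA array, so that 48.9% of them were higher. In the authors' deposited normalized values these counts were 369 and 190, with 66.0% higher and a median difference of 0.12 over all genes. Scaling to the spike-in RNAs gave 1169 and 68, with 94.5% higher and a median over all genes of 0.54. Directions below are therefore relative to the bulk of the genes. Between the arrays 5.59% of 16840 probes differed at least 2-fold, against 0.69% of spot pairs of the same probe within the control array and 0.12% within the Pla2g4c siRNA array. In 53 of the 56 genes with several measured probes and a difference of at least 2-fold, all probes differed in the same direction.

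**Figure D1:**
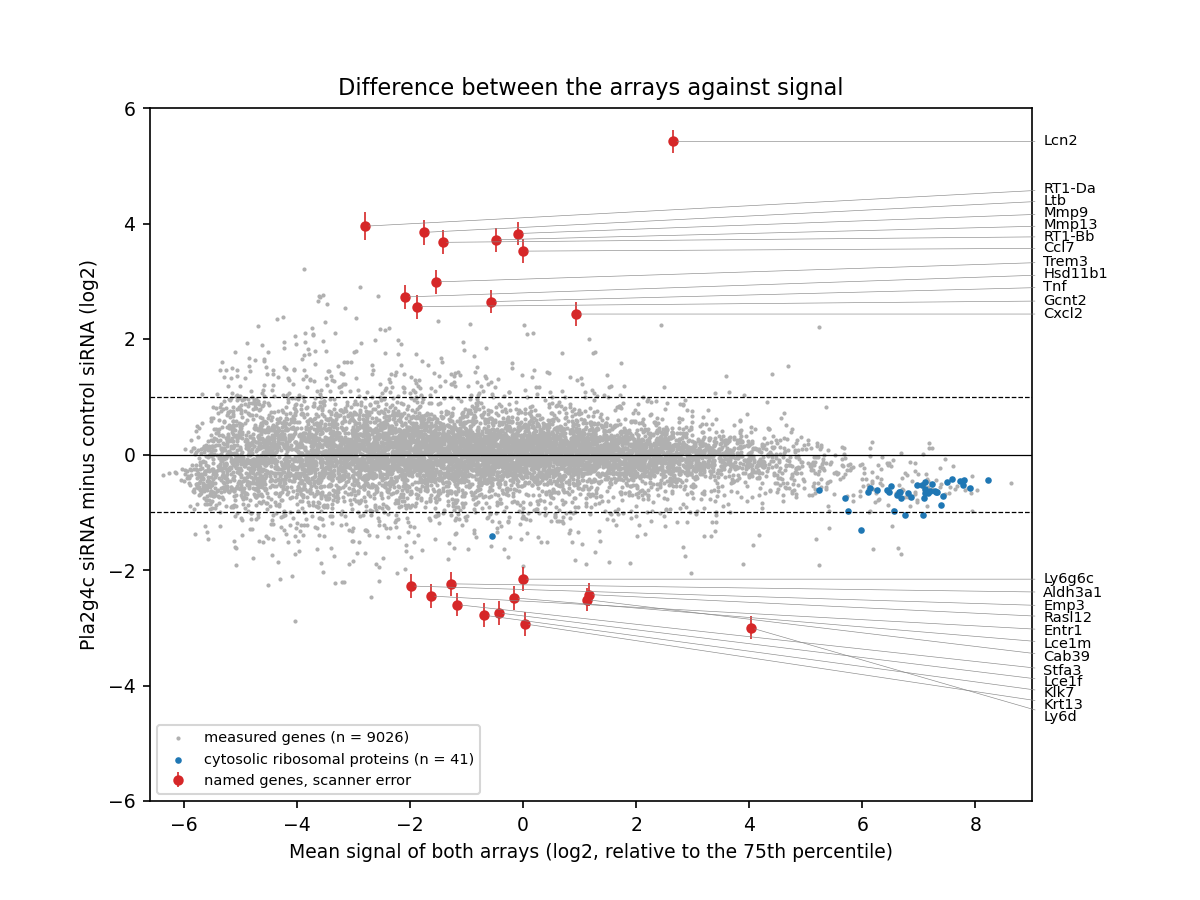
Difference between the arrays (Pla2g4c siRNA minus control siRNA, log2) against the mean signal of both arrays (log2, relative to the 75th percentile), with 1 point per gene for 9026 genes and dashed lines at 2-fold. The 24 named genes (red, bars are the scanner software's error) lie from -2.999 (Ly6d) to 5.42 (Lcn2), and the 41 measured members of the ribosomal protein list (blue) lie below 0, nearly all at the right, where other genes of high signal also lie mostly below 0.

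The highest difference was that of Lcn2, a secreted iron-siderophore binding protein of innate immunity, at 42.8-fold (5.42 ± 0.20). Among genes that met the naming rule, the MHC class II genes RT1-Da (15.5-fold, 3.95 ± 0.24) and RT1-Bb (12.8-fold, 3.67 ± 0.21) followed. With them came the cytokine Ltb (14.4-fold, 3.85 ± 0.21) and the matrix metalloproteinases Mmp9 (14.2-fold, 3.83 ± 0.20) and Mmp13 (13.2-fold, 3.72 ± 0.21). Measured probes without a symbol here reached 4.51. The chemokines Ccl7 and Cxcl2 were 11.5-fold and 5.40-fold higher, and the cytokine Tnf was 6.27-fold higher. Trem3, a myeloid receptor, was 7.94-fold higher, Hsd11b1, which regenerates active glucocorticoid, 6.63-fold, and Gcnt2, a glycosyltransferase, 5.90-fold. RT1-Bb and Trem3 rested on 1 spot each. For the others of the 24 genes named by the highest or lowest difference, every spot on the Pla2g4c siRNA array lay on the same side of every spot of that probe on the control array.

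Among genes that met the naming rule, the lowest difference was that of Ly6d, a surface protein of stratified epithelia, at 7.995-fold lower (-2.999 ± 0.20). Measured probes without a symbol here reached -4.17. The keratin Krt13 was 7.64-fold lower (-2.93 ± 0.20), the skin protease Klk7 6.89-fold lower (-2.78 ± 0.20), and the late cornified envelope genes Lce1f and Lce1m 6.69-fold and 5.59-fold lower. The protease inhibitor gene Stfa3 was 6.06-fold lower, the aldehyde dehydrogenase Aldh3a1 4.72-fold, and the Ly6 family member Ly6g6c 4.46-fold. Cab39, which encodes an activator of the LKB1 kinase complex, was 5.71-fold lower, Entr1 5.47-fold, Rasl12 5.37-fold and Emp3 4.85-fold. Each of the 24 named genes differed at least 2-fold in the same direction under every processing alternative that measured it, which the naming rule itself required for normexp and quantile normalization.

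Some genes were well above background on 1 array only and have a bound. There were 231 such genes on the Pla2g4c siRNA array and 85 on the control array, and the bound reached 2-fold for 72 and 44 of them. The background flag was set on the signal before scaling, and the Pla2g4c siRNA array was the brighter (75th percentile 1105 against 852). These counts therefore do not compare gains with losses. Fabp4, a fatty acid binding protein, was at least 11.2-fold higher, the chemokine Ccl3 at least 11.0-fold, Rassf4 at least 10.5-fold and Wfdc21 at least 10.2-fold. In the other direction, Garin3 was at least 34.6-fold lower, Tmem89 at least 23.3-fold, Zp1, a protein of the egg coat, at least 15.6-fold, and Wnt8b, a Wnt ligand, at least 14.9-fold. Each of these genes with a bound rested on 1 probe, and their spots were not compared one by one, so artefacts of single spots stay open for them. All bounds were computed under the main processing only. Each "at least" therefore holds for that background subtraction, and its size under normexp or another alternative was not computed.

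Gene lists fixed before the data were examined were described by their median difference and its percentile among 10000 random lists of genes of like signal, as a description of these 2 arrays. Of 31 lists with at least 5 measured members, 6 lay outside the central 95% of random lists, where 1.55 would by chance. In the list of NF-kB and inflammatory cytokines 17 of 18 members were above 0 and the median of 1.06 lay above all random lists. Lcn2 and Ccl7 were its highest members, and Tnip1, an inhibitor of NF-kB signalling (-0.45 ± 0.20), and the cytokine Lif (0.26 ± 0.25) its lowest. Beside Lcn2, Ccl7 and Cxcl2, the members at least 2-fold higher, named after their values were seen, were Ccl2 (2.21), Csf3 (1.53), Ccl5 (1.52), Ccl20 (1.17), Il1a (1.08), Cxcl1 (1.08) and C3 (1.03). The interferon-stimulated genes and RNA sensors had a median of -0.03 over 25 members, at percentile 41.6, with Cxcl10 at 1.32 ± 0.20 and Oas1a at 0.66 ± 0.21 and, lowest, Gbp2 at -1.01 ± 0.20 and Eif2ak2 at -0.97 ± 0.22.

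**Figure D2:**
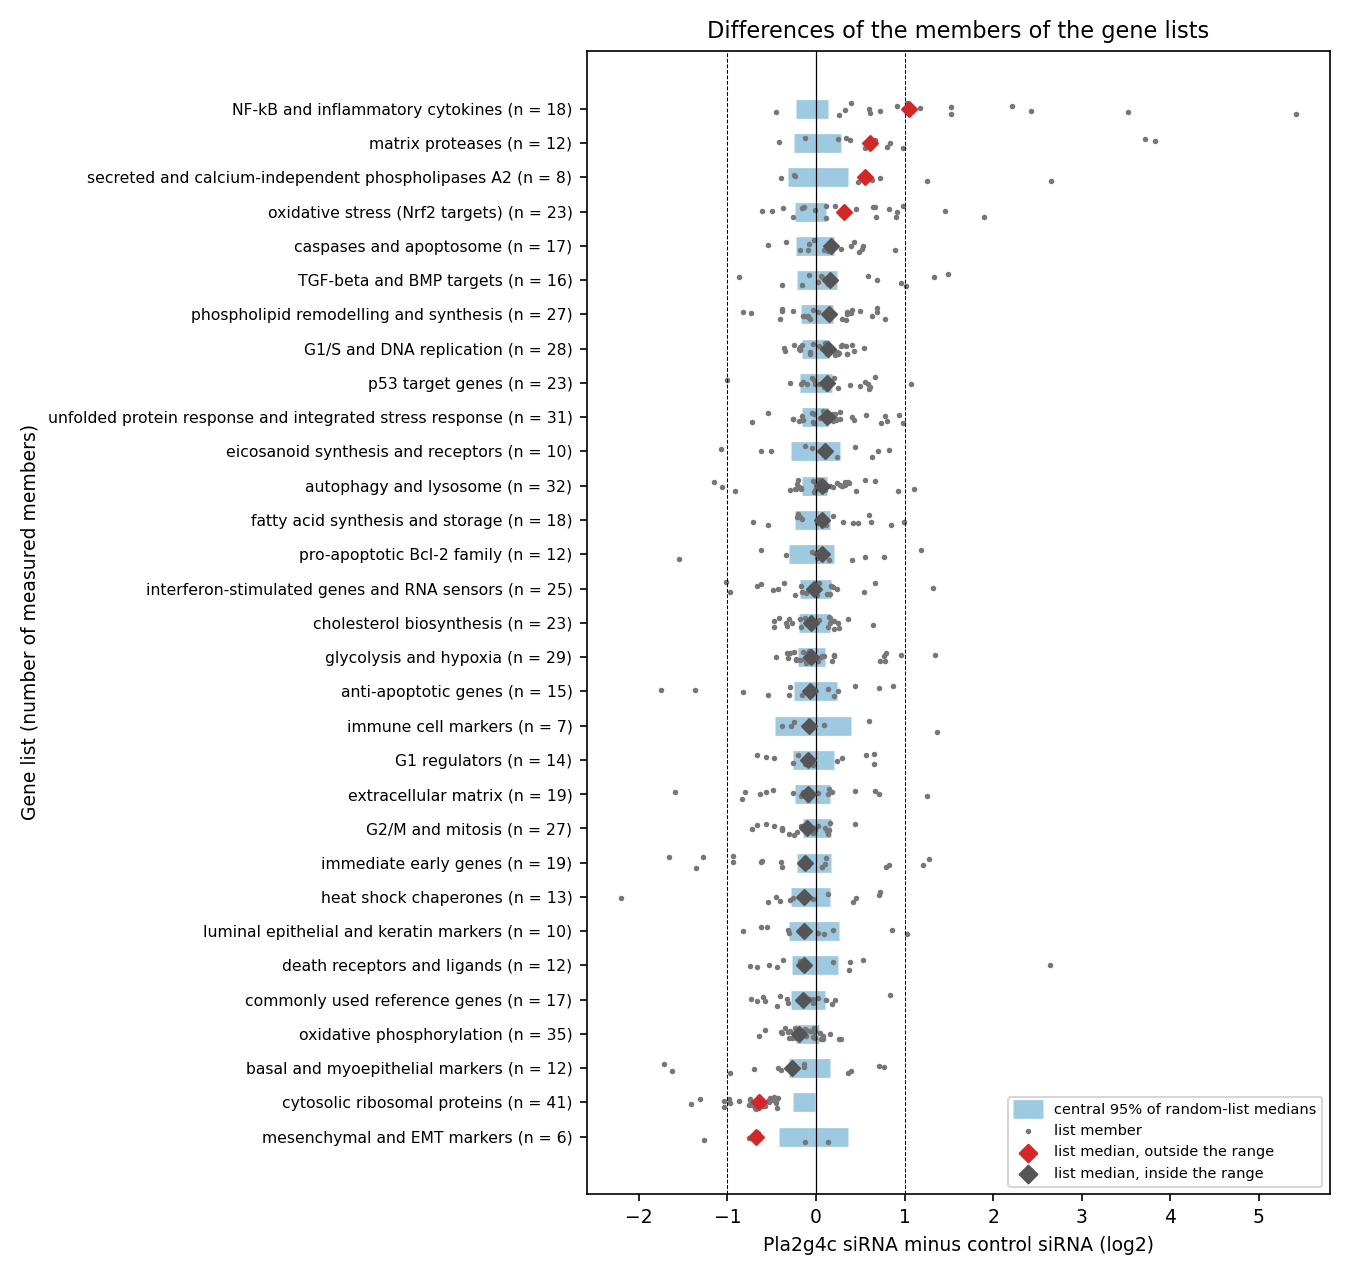
Difference of each measured member (grey points, Pla2g4c siRNA minus control siRNA, log2) in the 31 gene lists with at least 5 measured members, with list medians (diamonds) and the central 95% of medians of random lists of like signal (blue bars). The 6 medians outside the bars (red) run from -0.68 for mesenchymal markers to 1.06 for inflammatory genes, and n is the number of measured members.

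The matrix proteases had a median of 0.61 over 12 measured members, at percentile 99.99, with Mmp9 and Mmp13 at least 2-fold higher and 0 at least 2-fold lower. Mmp15 (-0.42 ± 0.23) and Mmp2 (-0.12 ± 0.23) were its lowest members, and 4 more members were well above background on the Pla2g4c siRNA array only. The extracellular matrix list had a median of -0.09 over 19 members, at percentile 27.2. Within it fibronectin, Fn1, differed by 1.25 ± 0.22, while Tgfbi differed by -1.59 ± 0.20 and Tnc by -0.83 ± 0.20. The TGF-beta and BMP targets had a median of 0.15 at percentile 90.0, with 3 of 16 members at least 2-fold higher. Inhba, an activin subunit, differed by 1.49 ± 0.20, Bambi by 1.33 ± 0.22, Id1 by -0.87 ± 0.20 and Bmp2 by -0.39 ± 0.26. Under normexp background correction the protease median was 0.33.

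Among lipid enzymes, the secreted and calcium-independent phospholipases A2 had a median of 0.56 over 8 measured members, at percentile 99.8. The secreted phospholipase Pla2g2a differed by 2.66 ± 0.25 and Pnpla2, a triglyceride lipase, by 1.25 ± 0.21, and the lowest members were Pla2g2d (-0.40 ± 0.21) and Pla2g3 (-0.25 ± 0.21). This median was -0.24, at percentile 38.8, when the 7 members not well above background on both arrays were let in. Eicosanoid synthesis and receptors (median 0.10 over 10 members, percentile 76.2) ranged from Ltb4r, a leukotriene B4 receptor (-1.07 ± 0.20), and Ptges (-0.62 ± 0.20) to Ptges2 (0.71 ± 0.20) and Tbxa2r (0.82 ± 0.25). In phospholipid remodelling and synthesis (median 0.14 over 27 members, percentile 91.3) 0 members differed 2-fold, and Lpcat4 (0.77 ± 0.21), Lpin2 (0.69 ± 0.29), Ptdss2 (-0.83 ± 0.20) and Agpat3 (-0.74 ± 0.21) were the extremes. Cholesterol biosynthesis had a median of -0.06 over 23 members, at percentile 32.6, with Mvd at 0.36 ± 0.20, and Hmgcs1 and Tm7sf2 both at -0.48. Fatty acid synthesis and storage had a median of 0.07 over 18 members, at percentile 85.9, with Dgat2 at 0.99 ± 0.20, Plin2 at 0.85 ± 0.20, Fads2 at -0.72 ± 0.34 and Scd2 at -0.55 ± 0.20. That list lay outside the random lists under quantile normalization, with a median of 0.23, and under cyclic loess, with 0.24.

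None of the 5 lists of cell death genes and p53 targets lay outside the random lists, although single members differed at least 2-fold. In the pro-apoptotic Bcl-2 family (median 0.06 over 12 members, percentile 79.5) Bid was 1.18 ± 0.20 and Bnip3 0.77 ± 0.20, and Bak1, an effector of mitochondrial permeabilisation, was -1.55 ± 0.20 and Bad -0.62 ± 0.20. Among anti-apoptotic genes (median -0.06 over 15 members, percentile 31.5) Bcl2 was -1.75 ± 0.22 and Birc2 -1.37 ± 0.20, and Birc3 was 0.87 ± 0.20 and Faim 0.71 ± 0.20. Caspases and the apoptosome had a median of 0.17 over 17 members, at percentile 95.3, with Apaf1, the apoptosome scaffold, at 0.89 ± 0.21, Diablo at 0.53 ± 0.20, Casp14 at -0.54 ± 0.21 and Htra2 at -0.34 ± 0.20. Death receptors and ligands had a median of -0.14 over 12 members, at percentile 16.0, with Tnf at 2.65 ± 0.20, Tnfrsf12a at 0.53 ± 0.20, Ripk1 at -0.74 ± 0.21 and Fadd at -0.66 ± 0.22. The p53 targets had a median of 0.12 over 23 members, at percentile 89.8, with Plk3 at 1.07 ± 0.21, Tigar at 0.67 ± 0.21, Perp at -1.003 ± 0.20 and Plk2 at -0.29 ± 0.20. With the brightest probe of each gene the p53 median was 0.20, at percentile 98.8.

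Of the stress lists, the Nrf2 targets of the oxidative stress response lay above all random lists, with a median of 0.31 over 23 members, 16 of them above 0. The glutathione S-transferase Gsta2 (1.89 ± 0.30) and the thioredoxin reductase Txnrd1 (1.46 ± 0.22) were at least 2-fold higher, and the ferritin light chain Ftl1 (-0.61 ± 0.20) and the thioredoxin Txn1 (-0.49 ± 0.20) were lowest. Quantile normalization gave this list a median of 0.55. The unfolded protein and integrated stress response had a median of 0.12 over 31 members, at percentile 95.8, with 0 members at 2-fold, and Slc7a11 (0.98 ± 0.23), Sdf2l1 (0.94 ± 0.20), Ddit4 (-0.73 ± 0.20) and Sel1l (-0.54 ± 0.30) as extremes. It lay outside the random lists under 5 alternatives, with medians of 0.18 under normexp and quantile normalization, 0.20 under cyclic loess and for probes above the median signal, and 0.15 without the filter on dim probes. Heat shock chaperones had a median of -0.14 over 13 members, at percentile 23.5, with Cryab, a small heat shock protein, at -2.20 ± 0.22, Bag3 at -0.54 ± 0.20, Hsph1 at 0.72 ± 0.21 and Hspb8 at 0.71 ± 0.20. Autophagy and lysosome genes had a median of 0.07 over 32 members, at percentile 89.0, with Wipi1 at 1.11 ± 0.21 and Neu1 at 0.93 ± 0.20, and the autophagy kinases Ulk1 at -1.15 ± 0.20 and Ulk2 at -1.06 ± 0.25. Under quantile normalization and cyclic loess their medians of 0.18 and 0.19 lay outside the random lists. Glycolysis and hypoxia genes had a median of -0.06 over 29 members, at percentile 45.5, with the carbonic anhydrase Car9 at 1.34 ± 0.20, Adm at 0.96 ± 0.20, Slc2a1 at -0.45 ± 0.20 and Pgk1 at -0.33 ± 0.20. Quantile normalization put this median at 0.18, outside the random lists.

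In the cell cycle lists 0 members differed 2-fold. G1/S and DNA replication genes had a median of 0.14 over 28 members, at percentile 96.1, from Tk1 (-0.36 ± 0.20) and Pola1 (-0.35 ± 0.21) to Fen1 (0.43 ± 0.20) and Cdc6 (0.54 ± 0.20). Quantile normalization and cyclic loess put their medians of 0.21 and 0.20 outside the random lists. G2/M and mitosis genes had a median of -0.10 over 27 members, at percentile 9.18, from Kif20a (-0.72 ± 0.20) and Cenpf (-0.67 ± 0.21) to Nek2 (0.15 ± 0.21) and Ccna2 (0.44 ± 0.20). G1 regulators had a median of -0.09 over 14 members, at percentile 30.1, with Ccnd3 and Cdk2 both at 0.66, Ccnd2 at -0.66 and Rbl2 at -0.56. Immediate early genes went both ways, with a median of -0.13 over 19 members, at percentile 14.2. Nr4a1 (1.28 ± 0.22) and Ccn1 (1.21 ± 0.23) were at least 2-fold higher, and Nr4a2 (-1.66 ± 0.21) and Klf4 (-1.36 ± 0.20) were lowest.

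The cytosolic ribosomal proteins had the list median of -0.64 at percentile 0 of the random lists, with 4 of 41 members at least 2-fold lower. Rpl15 (-1.41 ± 0.20) and Rps7 (-1.31 ± 0.20) were lowest, and Rplp0 (-0.44 ± 0.20) and Rps27 (-0.43 ± 0.20) highest. Matching in 10 bins of signal was too coarse for this list, since the 20 other genes nearest in signal to each member had a median difference of -0.35. Against those genes the ribosomal proteins differed by a median of -0.26, with all 41 below. The list median was -0.10 under quantile normalization and -0.27 under cyclic loess. Oxidative phosphorylation genes had a median of -0.19 over 35 members, at percentile 8.38, with Uqcrc1 at -0.64 ± 0.20, Ndufa1 at -0.57 ± 0.20, Ndufa9 at 0.29 ± 0.20 and Sdhd at 0.26 ± 0.20. The commonly used reference genes had a median of -0.14 over 17 members, at percentile 29.8, with Ywhaz at 0.83 ± 0.20, Hprt1 at 0.22 ± 0.20, Eef1a1 at -0.74 ± 0.20 and Rpl13a at -0.67 ± 0.20.

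Among cell type markers, the mesenchymal and EMT list had a median of -0.68 over 6 measured members, at percentile 0.06. The calcium-binding protein S100a4 differed by -1.27 ± 0.20 and vimentin, Vim, by -0.76 ± 0.20, with Twist1 at -0.13 ± 0.21 and Col1a1 at 0.13 ± 0.21. With dim members let in, the median was -0.33 at percentile 5.37. Basal and myoepithelial markers had a median of -0.27 over 12 members, at percentile 4.88, with the keratins Krt5 (-1.72 ± 0.20) and Krt17 (-1.63 ± 0.20) lowest and Mylk (0.77 ± 0.21) and Krt15 (0.71 ± 0.20) highest. With the brightest probe of each gene that median was -0.41, and without the filter on dim probes -0.34, both outside the random lists. Luminal markers had a median of -0.14 over 10 members, at percentile 19.9, with the adhesion molecule Epcam at 1.03 ± 0.20, Krt8 at 0.86 ± 0.27, Ehf at -0.82 ± 0.24 and Cdh1, E-cadherin, at -0.63 ± 0.20. Krt8 was dim on both arrays, and its difference was 0.11 under normexp. Of 12 milk protein genes 10 were not well above background on either array, and Csn1s1 (-0.60 ± 0.22) and Xdh (-0.15 ± 0.20) were measured.

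Immune cell markers had a median of -0.08 over 7 measured members, at percentile 40.2. The macrophage gene Aif1 differed by 1.37 ± 0.20 and lysozyme, Lyz2, by 0.60 ± 0.34, and Cd68 by -0.39 ± 0.21 and Cd3d by -0.28 ± 0.21. The pan-leukocyte marker Ptprc and 7 more markers were not well above background on either array. Of the endothelial and adipocyte markers 2 were measured, Eng at 2.11 ± 0.22 and Cdh5 at -0.40 ± 0.23.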

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

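Spike-in scaling was chosen only after the results were seen, and the other alternatives before. Each of the 24 named genes stayed at least 2-fold in its direction under all alternatives that measured it. The naming rule required this for normexp and quantile normalization. The constant shifts of median, deposited and spike-in scaling were too small to undo it, and for genes with 1 probe the choice of probes could not. The counts of 263 higher and 275 lower genes were 116 and 154 under normexp, 1169 and 68 under spike-in scaling, 539 and 765 without the filter on dim probes, 79 and 119 for probes above the median signal, 784 and 929 at 1.5-fold, 85 and 65 at 3-fold, and 558 lower for probes. The filters and thresholds differ by construction in what they count, and spike-in scaling shifted every gene by 0.55. Normexp added an offset of 50 to every spot. The median processed signal was 66.7 on the control array and 86.9 on the Pla2g4c siRNA array. By construction the offset shrinks the differences of dim genes, and its share in the lower counts was not tested. Under spike-in scaling the list medians were 1.103 for secreted and calcium-independent phospholipases A2, 0.86 for Nrf2 targets, 1.60 for NF-kB and inflammatory cytokines, 1.16 for matrix proteases, -0.13 for mesenchymal markers and -0.10 for ribosomal proteins. Ribosomal proteins were at -0.10 under quantile normalization and -0.27 under cyclic loess, and Nrf2 targets at 0.55 under quantile normalization. Matrix proteases were at 0.33 under normexp and 0.84 for probes above the median signal. Without the filter on dim probes the phospholipase median turned to -0.24 and the mesenchymal median was -0.33, both inside the random lists, since dim members entered. For the other list medians the cause was not tested, and those under normexp carry the same offset. Of 307 list values under alternatives 258 stayed within 0.20 of the main value and the others moved further. The sign changed in 43, of which 15 were under spike-in scaling, 9 in the deposited values and 1 in a list apart from the random lists, the phospholipases. The side of the random-list limit changed in 17, with 15 gained over 7 lists and 2 lost. Of the gene values under alternatives 1179 stayed within their scanner error, 243 moved further and 0 of those at 2-fold changed sign. Signal over background limits the dim genes, and the Pla2g4c difference was run under no alternative, as no probe was matched.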

Other observations

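The tests of spike-in level, signal level, interferon response, single spots of class II genes and choice of squamous genes and the lists of squamous, MHC class II and glutathione S-transferase genes were chosen only after the results were seen, while the tests of myeloid genes and of single spots of inflammatory genes were set before their values were seen. The myeloid test replaced a test on the median of the immune cell markers (-0.08) after that median was seen. A test of array scaling on the ribosomal list was dropped after its values were seen. Both of these earlier tests had argued against their explanation. MHC class II genes stood together. Of 7 measured, 6 were at least 2-fold higher in the Pla2g4c siRNA array, and all 7 lay above 0 under each scaling, with a median of 2.19 that normexp brought to 1.45. Beside RT1-Da and RT1-Bb these were the invariant chain Cd74 (4.72-fold), RT1-Db1 (4.56-fold), the class II transactivator Ciita (3.92-fold) and RT1-DMb (2.56-fold), with RT1-DMa at 1.42-fold. The 13 class I genes of the RT1-A and RT1-CE groups had a median of 0.09, from -0.28 to 0.25. The alpha-class glutathione S-transferases Gsta1 (4.52-fold), Gsta3 (4.21-fold), Gsta2 (3.72-fold) and Gsta5 (2.79-fold) were higher too, and Gsta4 was at 1.25-fold. Normexp brought the median of these 5 genes from 1.89 to 0.61. The offset of normexp shrinks the differences of dim genes by construction. The share of the offset in this fall and in that of the class II median was not tested.

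Families of genes sharing a symbol stem were scanned, and 34 of 296 lay outside the central 95% of random lists, where 14.8 would by chance. The kallikreins parted. Klk8 (2.61), Klk9 (1.67), Klk10 (1.56) and Klk11 (1.23) were at least 2-fold higher, while Klk6 was at -0.68 and Klk7 at -2.78. Under normexp Klk8 and Klk9 remained at least 2-fold higher, and the median of the 6 kallikreins was 0.87 in place of 1.39. Of 21 keratins 7 were at least 2-fold lower and 3, Krt81 (1.74), Krt82 (1.61) and Krt23 (1.52), at least 2-fold higher. Those counts were 7 lower and 1 higher, Krt81, under normexp, and 6 and 6 under spike-in scaling.

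The low values of Ly6d, Krt13, Klk7 and Lce1f led to a list of squamous differentiation genes, of which 25 were measured. All 25 were lower, or 22 under spike-in scaling, and 20 were at least 2-fold lower, with a median of -1.78. Of the measured kallikreins the list held Klk7 only. It left out Klk8 (2.61), Klk9 (1.67), Klk10 (1.56) and Klk11 (1.23), which were higher, and Klk6 (-0.68), so the count depends on which family members were listed. Aldh3a1, Stfa3 and Ly6g6c, first listed for their low values, were taken out again. This count is partly circular, since 15 of the 25 had been seen when the list was made. Of the members that had not been seen, 10 of 10 were lower as well, with a median of -1.16 and 6 at least 2-fold lower, among them Dmkn (3.55-fold), Cnfn (3.23-fold) and Tgm3 (2.96-fold). The choice of genes after their values were seen therefore does not account for the whole pattern, and a lower squamous programme may be a feature of the Pla2g4c siRNA culture. Under spike-in scaling 8 of those 10 were below 0. Culture density and time were not tested, and with 1 culture per group they stay open beside the siRNA.

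For the inflammatory and MHC class II transcripts, myeloid cells in the culture would bring their other abundant transcripts. Of 25 myeloid genes with a probe, 2 were at least 2-fold higher, Lcp1 (4.58-fold) and, by bound, Fgr (at least 2.54-fold), and 16 were not well above background on either array. The bound set to exclude such cells was met, but it counted genes at the floor, which exclude nothing, and only 8 were well above background on at least 1 array. Outside that list Trem3 and Aif1, at 7.94-fold and 2.58-fold, and by bound Mmp12 (at least 7.81-fold) and Tlr2 (at least 6.29-fold) go with such cells, while the measured C1qb (-0.92), Fcgr2b (-0.42), Laptm5 (0.09), Cd68 (-0.39), Cd14 (-0.25) and Fcer1g (-0.08) go against them, and they stay open. The interferon-stimulated list had a median of -0.026 with 1 of 25 members at least 2-fold higher. That argues against a broad interferon response to transfected RNA that was stronger with the Pla2g4c siRNA. Both cultures were given an siRNA, so a response shared by both cannot be seen in the difference. The Oas genes, from the scan of symbol stems, had a median of 0.41 over 6 measured, at percentile 97.8, with 0 at 2-fold. Every spot on the Pla2g4c siRNA array exceeded every spot on the control array for 10 of 10 inflammatory genes and for 4 of 4 class II genes with several spots, which argues against artefacts of single spots in the MHC class II genes and inflammatory genes covered, but RT1-Bb and RT1-Db1 rest on 1 spot each. A response of the tumour cells may remain. It could be to a loss of Pla2g4c, to another target of the siRNA or to a difference between the cultures. Whether Pla2g4c was lowered was not measured here, and these data do not separate these possibilities.

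For the ribosomal protein transcripts, a part of the difference was shared by other genes of like signal. The spike-in RNAs well above background showed no such fall at high signal. Before scaling, the dimmest of them (log2 signal 7.10) differed by -0.21 and the brightest (17.4) by -0.15. Over that range this argues against a bias of the arrays that depends on signal. The other genes nearest in signal had a median of -0.35 beside the list's -0.64. That met the bound set for such a bias as a part of the cause. A real difference of other bright genes would give the same median, so that test cannot decide it, and a part stays open. The ribosomal proteins lay a further -0.26 below those genes and kept a median of -0.27 after cyclic loess. Both values argue against such a bias as the whole cause. Quantile normalization left -0.10, so the size of the remainder is open. The bounds of these tests were set with the values known. Against the spike-in RNAs the list median was -0.10, within the bounds set for no decision, so a lower level of these transcripts and a higher level of the others cannot be told apart on 1 array per group.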
